A study of Mus musculus with 3 samples.

How the data were processed

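Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse embryonic stem (ES) cells in 3 libraries. The control library used an antibody against the HA tag in cells without a transgene. The ZFP57 library used the same antibody in cells that expressed HA-tagged ZFP57, and the KAP1 library used an antibody against KAP1 (RBCC) in E14 ES cells without a transgene. Per the labels' protocols, chromatin was fixed with paraformaldehyde, sonicated and isolated with antibody. Each group holds 1 library, so no replicate spread could be measured and no test between conditions was made.

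For each library the authors deposited 1 list of genomic regions with a chromosome, a start and an end. The files have no header and no score, height, fold or depth column. Every region in the 3 lists is 150 bp wide, and no region is listed more than once. Per the submitters' processing notes, Bowtie, a short-read aligner, and the mouse genome build mm9 were used. The Bowtie version, the peak caller, its threshold, the treatment of reads that map to several places and any subtraction of a control are not given in the sources used here. The regions extend beyond the last gene of the GRCm38 gene table on 10 chromosomes, but chromosome lengths of either build were not compared here, and the build is taken from the notes. Sequencing depth is unknown. The number of regions in a list moves with depth and threshold as well as with binding, so list lengths were not read as amounts of binding.

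The planned results that need gene positions or sequence of build mm9 were not run, because neither is used here. These are the imprinted loci, the other imprinted genes, zinc finger, pluripotency, lineage, housekeeping, protocadherin and olfactory receptor genes by distance, the position of regions to genes, the Zfp57 and Trim28 loci and the hexamer counts. For the same reason no region is given a gene name. The GRCm38 RefSeq gene table supplied gene numbers per chromosome (21900 protein-coding genes, 367 named Zfp followed by digits and 1110 olfactory receptor genes), and none of its coordinates was used for annotation. The rule fixed before the data were examined named the 10 widest regions where no score was given. It selected none, since all widths were equal. The 1 Mb windows and shared loci named in the text were therefore chosen after their values were seen. They follow the rules given with them and, where no rule is given, are examples.

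Overlap was counted from 1 bp. The counts for the 6 ordered pairs of lists were checked against bedtools 2.31.1 and were identical. Regions of the ZFP57 and KAP1 lists that overlapped a control region were treated as background of the method, and sharing was then counted among the rest. Chance was measured by placing the regions of the first list at random on their own chromosome 1000 times, between the lowest and the highest position seen there in any list. A second measure moved each region by 50 to 500 kb in a random direction 200 times. Because the median distance between neighbouring regions of a list is shorter than that, a move of 0.5 to 5 kb was added after seeing the data, also 200 times. All 3 ignore which sequences short reads can be mapped to. Regions placed at random or moved by 50 to 500 kb were also not kept away from control regions. Where regions near the control were left out, these chance values therefore tend to be too low. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Because regions lie in clusters, a second 95% interval was taken from 1000 draws of 1 Mb windows with replacement. Counts per window or chromosome carry exact 95% Poisson intervals, which also cover counting error only. Distances to the nearest control region were compared with a two-sided permutation test of 100000 resamples over regions, on the log10 scale. Regions are not replicates, so that test describes these libraries at most. It also ignores that regions lie in clusters, so its p-values can be too small. Isolated regions were those with no other region of their own list within 10 kb.

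The overlap code was tested on simulated lists as long as the real ones: all 2000 planted pairs were found, and 2 unrelated lists overlapped at 166 regions against a chance mean of 168 with an SD of 12.1. The simulated lists were placed at random, without clusters, in the same way as for the chance value. This checks the code and not how well random placement suits clustered lists. Alternatives changed the overlap that counts, the merging of regions, the mitochondrial sequence, the treatment of background and the length of the control list. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.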

Results

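Enriched regions were listed for 3 ChIP-seq libraries of mouse ES cells, which are pluripotent cells derived from the early embryo. ZFP57 is a KRAB zinc finger protein known for keeping DNA methylation at imprinted loci, and KAP1 (also called TRIM28) is the corepressor that KRAB zinc finger proteins recruit. The HA ChIP from cells without a transgene listed 45956 regions, the HA ChIP from cells with HA-ZFP57 listed 22031, and the KAP1 ChIP listed 20870. All regions were 150 bp wide and covered 6.88, 3.29 and 3.11 Mb. The control list was thus 2.09 times as long as the ZFP57 list and 2.20 times as long as the KAP1 list. With 1 library per group there were no replicates, and the depth of each library is unknown.

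The first comparison asked which regions of the HA-ZFP57 library were absent from the HA ChIP without the transgene. Of the 22031 ZFP57 regions, 10800 overlapped a control region and 11231 did not. The overlapping share was 49.0% (exact 95% interval 48.4 to 49.7%, interval over 1 Mb windows 44.5 to 52.9%), against 0.776% for regions placed at random and at most 0.958% in 1000 placements. Of the overlapping ZFP57 regions, 70.5% had their midpoint within 50 bp of a control midpoint, where offsets spread evenly over all overlaps would give 33.8%. The regions common to all 3 lists made up 34.9% of the ZFP57 list (7681 regions), those shared with the control alone 14.2%, those shared with KAP1 alone 9.80%, and those in neither other list 41.2%.

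Several of the densest parts of the genome held similar numbers of regions in the 3 libraries, and others did not. The 1 Mb window with the most control regions, chromosome 17 from 6 to 7 Mb (mm9), held 777 control, 711 ZFP57 and 720 KAP1 regions. Chromosome 8 from 19 to 20 Mb held 559, 526 and 547, and chromosome 1 from 87 to 88 Mb held 387, 373 and 387. By contrast, chromosome 17 from 13 to 14 Mb held 279 control, 202 ZFP57 and 133 KAP1 regions, and chromosome 4 from 146 to 147 Mb held 466, 508 and 661. The 51 windows with at least 100 control regions held 21.7% of the control list, 40.3% of the ZFP57 list and 45.7% of the KAP1 list. Across the 2514 windows with a region, Spearman's rho was 0.74 between ZFP57 and control counts, 0.56 between KAP1 and control counts and 0.62 between ZFP57 and KAP1 counts. These are correlations across windows, which are not replicates. The mitochondrial genome held 42 control, 41 ZFP57 and 38 KAP1 regions.

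Of the 115 windows with at least 30 ZFP57 regions, 21 held more ZFP57 than control regions, although the ZFP57 list was 0.479 times as long. From 20 ZFP57 regions upward there were 28 such windows, and in 0 of them did the Poisson intervals of both counts lie apart. These are raw counts, not scaled to list length. The window with the largest ratio, chromosome 3 from 113 to 114 Mb, held 23 ZFP57 regions (95% Poisson interval 14.6 to 34.5) and 10 control regions (4.80 to 18.4). It also held 26 KAP1 regions. Next by ratio was the X chromosome from 72 to 73 Mb, with 27 ZFP57 (17.8 to 39.3), 19 control (11.4 to 29.7) and 19 KAP1 regions. It was followed by chromosome 14 from 52 to 53 Mb, with 47 ZFP57 (34.5 to 62.5), 34 control (23.5 to 47.5) and 26 KAP1 regions.

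The second comparison set the KAP1 ChIP against the same control, which was made with another antibody. Of the 20870 KAP1 regions, 9838 overlapped a control region, a share of 47.1% (exact 95% interval 46.5 to 47.8%, interval over windows 42.6 to 51.4%) against 0.777% by chance. The remaining 11032 regions did not. KAP1 regions were clustered more tightly than those of the other libraries: 57.5% had another KAP1 region within 1 kb, compared with 48.2% in the ZFP57 list and 28.8% in the control list. The median distance to the nearest region of the same list was 652 bp for KAP1, 1160 bp for ZFP57 and 6407 bp for the control.

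In 47 of the 115 windows with at least 30 KAP1 regions, KAP1 regions outnumbered control regions, although the KAP1 list was 0.454 times as long. These windows held 33.5% of the KAP1 list, 24.8% of the ZFP57 list and 12.3% of the control list, and KAP1 regions also outnumbered ZFP57 regions in all 47. They lay on 14 chromosomes, with 7 each on chromosomes 7 and X, 6 on chromosome 12 and 5 on chromosome 13. Neighbouring windows were joined into blocks, of which the largest and the 5 with the highest ratio of KAP1 to control regions are given. The largest block, chromosome 4 from 145 to 148 Mb, held 1448 KAP1 regions (Poisson interval 1374 to 1525), 1153 ZFP57 regions (1087 to 1222) and 1072 control regions (1009 to 1138). Chromosome 13 from 62 to 63 Mb held 126 KAP1 (105 to 150), 56 ZFP57 (42.3 to 72.7) and 61 control regions (46.7 to 78.4). Chromosome 2 from 177 to 178 Mb held 67 KAP1 (51.9 to 85.1), 28 ZFP57 (18.6 to 40.5) and 33 control regions (22.7 to 46.3). Chromosome 7 from 9 to 11 Mb held 325 KAP1 (291 to 362), 191 ZFP57 (165 to 220) and 212 control regions (184 to 243). Chromosome 8 from 22 to 23 Mb held 38 KAP1, 23 ZFP57 and 25 control regions, with overlapping intervals, and chromosome 12 from 22 to 25 Mb held 194 KAP1 (168 to 223), 86 ZFP57 (68.8 to 106) and 130 control regions (109 to 154). Some of the 47 windows were near ties. The Poisson intervals lay apart from the control in 6 and from ZFP57 in 12, and chromosome 8 from 71 to 72 Mb held 99 KAP1 and 97 control regions. The windows were chosen for holding more KAP1 than control regions, and each count comes from 1 library, so the 6 are no test of a difference.

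**Figure D1:**
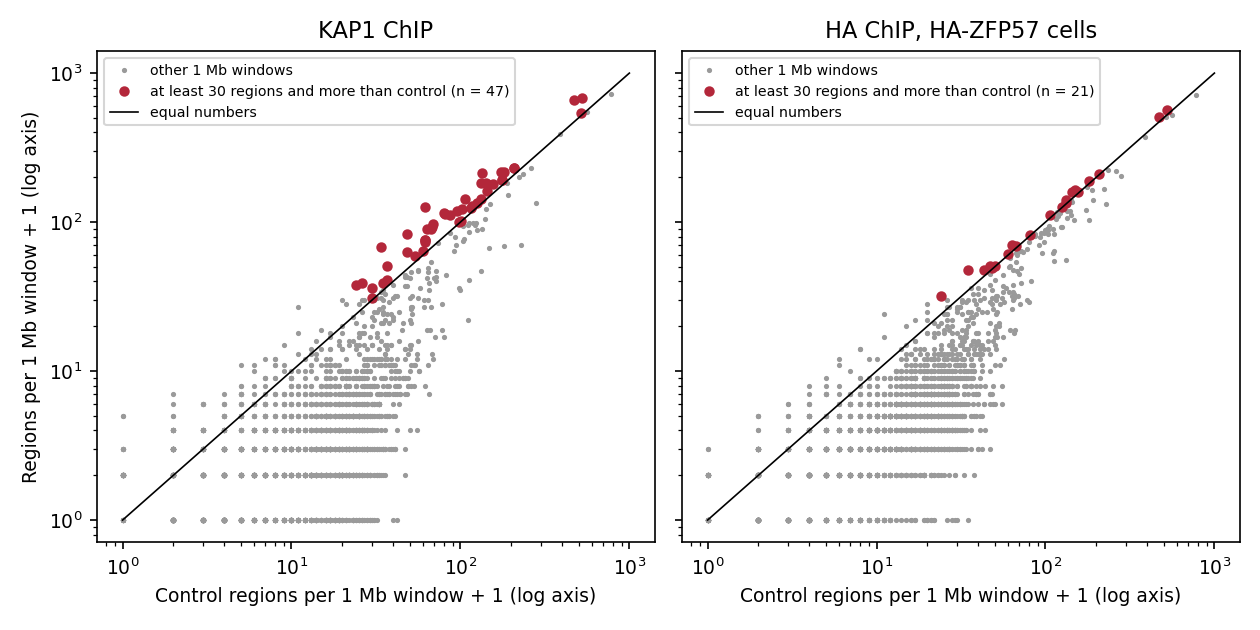
Each point is a 1 Mb window of build mm9, with the number of control regions on the x axis and the number of KAP1 (left) or ZFP57 (right) regions on the y axis, both plus 1 on log axes; the line marks equal numbers. Windows with at least 30 regions and more than the control are red: 47 for KAP1, several well above the line, and 21 for ZFP57, which lie closer to it.

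Some windows held control regions almost alone. Among the 178 windows with at least 40 control regions, the 10 with the lowest share of the other libraries included 6 on chromosome 8. Chromosome 4 from 139 to 140 Mb held 41 control regions, 2 ZFP57 regions and 0 KAP1 regions, and chromosome 8 from 91 to 92 Mb held 40, 3 and 2. Chromosome 17 from 30 to 31 Mb, among the densest of the control, held 226 control, 131 ZFP57 and 69 KAP1 regions.

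The third comparison asked whether HA-ZFP57 and KAP1 regions lay at the same sites. The KAP1 library came from cells without the transgene, so sharing cannot show that both proteins sat together in the same cells. Over all regions, 9839 ZFP57 regions (44.7%, interval over windows 39.5 to 49.5%) overlapped a KAP1 region, and 9904 KAP1 regions (47.5%) overlapped a ZFP57 region. After regions overlapping a control region had been left out of both lists, 1957 of 11231 ZFP57 regions overlapped a KAP1 region. This was 17.4% (exact 95% interval 16.7 to 18.1%, interval over windows 15.3 to 19.97%), against 0.152% for random placement, a ratio of 115, and 0.789% after moving each region by 50 to 500 kb, a ratio of 22.1. After a move of 0.5 to 5 kb, which stays closer to local clusters, it was 2.67%, and the observed share was 6.52 times that. In the other direction 1966 of 11032 KAP1 regions (17.8%, interval over windows 15.8 to 19.6%) overlapped a ZFP57 region. Midpoints lay within 50 bp of each other in 68.4% of the shared ZFP57 regions.

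Shared regions lay closer to control regions than the rest did, even though none overlapped one. The median distance to the nearest control region was 679 bp for the 1957 shared ZFP57 regions and 7015 bp for the 9274 others (permutation test over regions, two-sided, p = 1e-05, the smallest that 100000 resamples can give). For KAP1 the medians were 674 bp for 1966 shared and 4058 bp for 9066 other regions (permutation test, p = 1e-05). Both tests treat single regions as independent although regions lie in clusters. Their p-values can therefore be too small, and the medians are given as description. The share of ZFP57 regions on KAP1 accordingly depended on how far from control regions it was counted. It was 10.02% beyond 1 kb, 6.14% beyond 10 kb (269 of 4382, interval over windows 5.31 to 6.98%) and 6.43% beyond 50 kb (95 of 1478, 5.13 to 7.76%). Random placement gave 0.042% beyond 10 kb and 0.0152% beyond 50 kb. The placed regions could land near control regions, where the filtered lists hold none, so both values are too low.

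**Figure D2:**
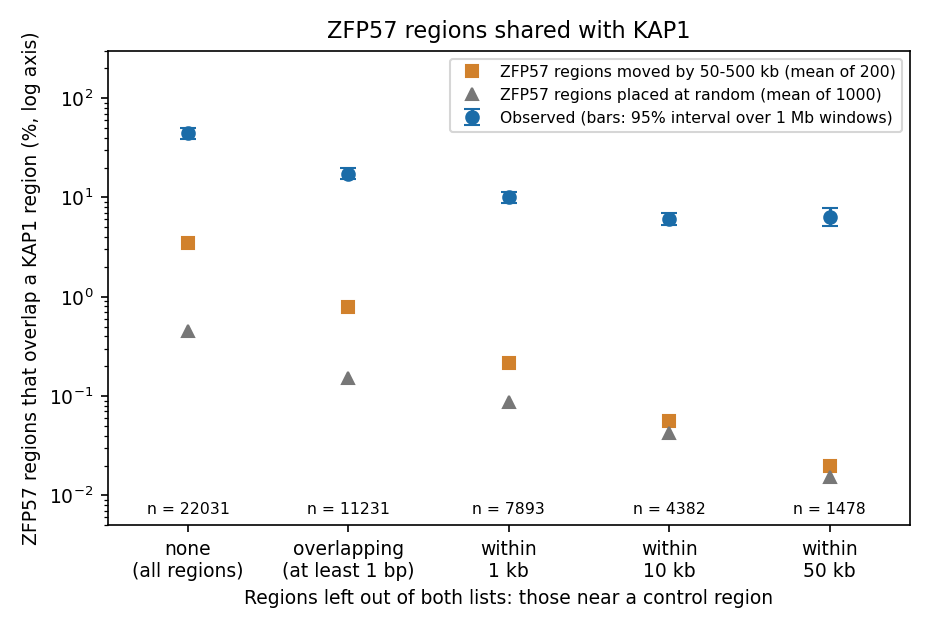
The share of ZFP57 regions that overlap a KAP1 region (percent, log axis) is plotted against which regions near a control region were left out of both lists, with bars for the 95% interval over 1 Mb windows. The observed share goes from 44.7% with all regions to 6.14% beyond 10 kb. At each distance it lies above regions moved by 50 to 500 kb (squares) and regions placed at random (triangles). Moved and placed regions were not kept away from control regions.

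The 269 shared ZFP57 regions more than 10 kb from any control region fell into 249 loci when those within 5 kb were joined. Of these loci 231 held 1 shared ZFP57 region, 16 held 2 and 2 held 3. Chromosome 14 had the most (24 loci), followed by chromosomes 7 and 10 (19 each), and chromosomes 18 and Y had 1 each. Per Mb, chromosome 14 held 0.196 loci, chromosome 10 0.150, chromosome 17 0.141, chromosome 15 0.129 and chromosome 7 0.127. The single locus on Y gave 0.345 per Mb, over a short span. The loci with 3 shared ZFP57 regions were chromosome 6 from 30687583 to 30688899, with 4 shared KAP1 regions and 64.4 kb from the nearest control region, and chromosome 15 from 72080111 to 72083654, with 3 shared KAP1 regions and 45.6 kb from the nearest control region. Loci with 2 shared regions of each library included chromosome 10 from 7885638 to 7890044, chromosome 10 from 79202118 to 79203097, chromosome 6 from 58856893 to 58857267, chromosome 5 from 50595830 to 50597854, chromosome 8 from 73524703 to 73527660 and chromosome 16 from 86821262 to 86821594. In the chromosome 6 locus at 58856893 the closest ZFP57 and KAP1 midpoints were 4 bp apart. On chromosome 14, 4 loci starting at 5510889, 5712046, 5892605 and 6696119 had the same span from first to last base (258 bp) and each held 2 ZFP57 regions and 1 KAP1 region. In each the closest ZFP57 and KAP1 midpoints were 24 bp apart. Whether the 4 are copies of 1 sequence to which the same reads map was not tested. They count as separate loci in the 249 and in the 24 of chromosome 14. The nearest gene of each locus was not analysed here.

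The other pairs of libraries gave a scale for this sharing. Each pair was counted among regions at least 10 kb from the third list. ZFP57 and control regions then coincided at 13.6% of 6929 ZFP57 regions, 40.02 times the random value (37.2 to 42.8 from the interval over windows). KAP1 and control regions coincided at 7.70% of 4726 KAP1 regions, 24.1 times the random value (21.3 to 27.0). ZFP57 and KAP1 regions coincided at 6.14% of 4382 ZFP57 regions, the lowest of these 3 shares, and at 146 times the random value (126 to 166), the highest of the 3 ratios. The control sets were longer (27918 and 25931 regions, against 3633 KAP1 regions), which raises both the share and the random value. Placed regions were not kept 10 kb from the third list, so the random values are too low and the ratios too high. The size of this error can differ between the pairs, so their ratios are not strictly comparable.

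Isolated regions, with no other region of the same list within 10 kb, numbered 19676 in the control list (42.8%), 7080 in the ZFP57 list (32.1%) and 4800 in the KAP1 list (23.0%). The X chromosome held 0.917 isolated control regions per Mb, 0.618 ZFP57 regions and 0.691 KAP1 regions, below every autosome in each list. Chromosome 8 held 10.4, 2.67 and 2.57 per Mb, which ranked 2, 13 and 2 among the 19 autosomes.

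**Figure D3:**
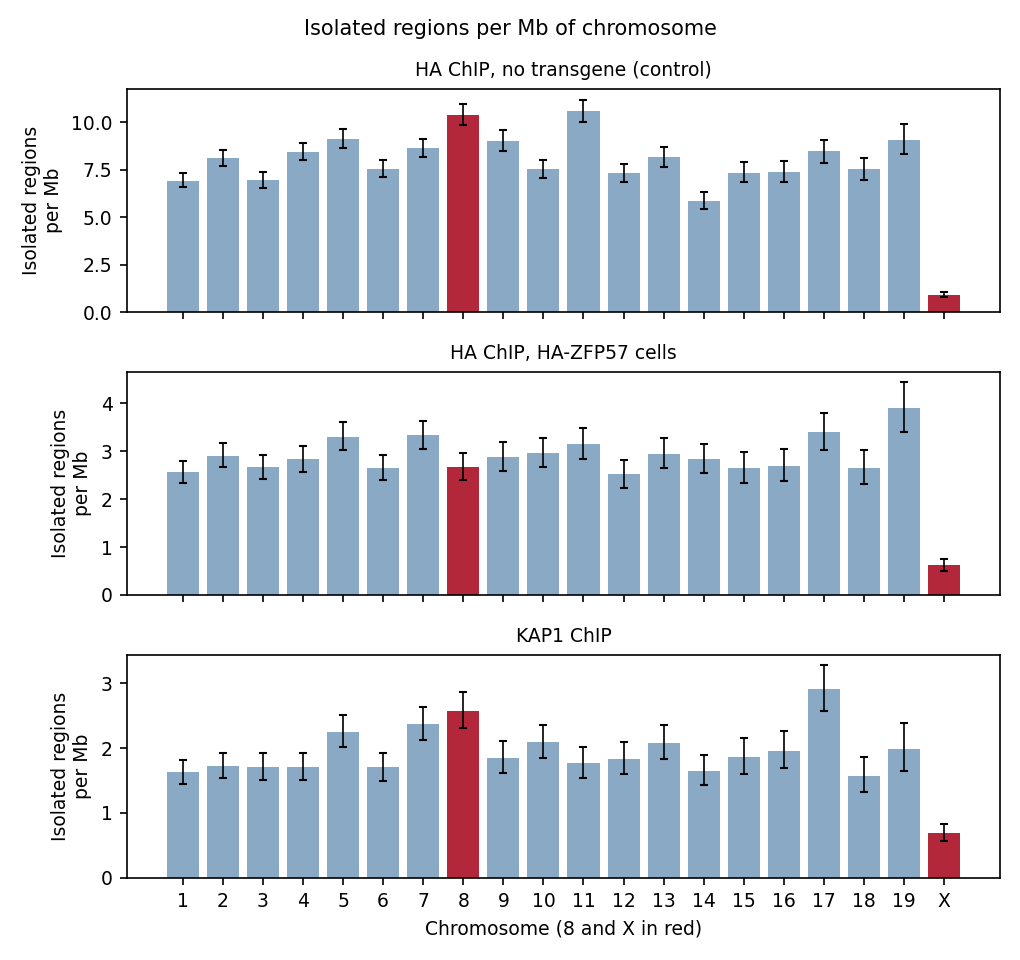
Bars give the isolated regions per Mb of each autosome and of X in each of the 3 libraries, with exact 95% Poisson intervals for counting error; chromosomes 8 and X are red. X is the lowest bar in each panel (0.917, 0.618 and 0.691 per Mb), and chromosome 8 is among the highest for the control and KAP1 but not for ZFP57.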

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

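With 1 library per group, no replicate could be left out. No paired analysis was possible because each group holds 1 sample. Alternatives on background distance, the shorter move, thinning, dense windows and the window counts were chosen after seeing the data; the others were fixed before the data were examined. Merging touching regions or dropping the mitochondrial sequence kept each of the 3 overlap shares within its exact interval. Requiring 75 bp of overlap gave 40.6% of ZFP57 and 37.3% of KAP1 regions on control regions. Of the ZFP57 regions that were left, 16.6% lay on KAP1. Midpoints within 500 bp gave 59.1%, 59.4% and 15.5%. Neither 16.6% nor 15.5% is a share of the same set as the 17.4% counted from 1 bp. The 75 bp rule kept regions with a shorter overlap with a control region, and the 500 bp rule left out more regions near one. Thinning the control list to the length of the other ChIP list gave 22.7% for ZFP57 and 23.0% for KAP1, a fall that random thinning gives by construction. The ZFP57 share on KAP1 was 44.7% with all regions kept, 10.02%, 6.14% and 6.43% without regions within 1, 10 and 50 kb of a control region, and 8.94% without 1 Mb windows holding 50 or more control regions. Its ratio to chance fell from 115 with random placement to 22.1 with moves of 50 to 500 kb and 6.52 with moves of 0.5 to 5 kb; the cause was not tested. All these shares stayed above their chance values where chance was computed. The count of 47 windows with more KAP1 than control regions was 50 with windows shifted by 0.5 Mb, 57 from 15 KAP1 regions upward and 46 after merging. The stricter threshold was not run, because the lists hold no score and all widths are equal, and the alternatives on gene distance, transcription start sites and the hexamer were not run with their results. Unknown depth and threshold limit every comparison of list lengths, and whether a region missing from a list lay just under its threshold was not tested.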

Other observations

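Some of the tests below were chosen after the values were seen. These are the comparison of library pairs and the midpoint distances with the move by 0.5 to 5 kb. The others are the values without chromosome 7 or 17 alone, and the comparisons of X and of chromosome 8 with gene number.

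Isolated regions, those without a neighbour of their own list within 10 kb, occurred on every autosome in each list. In the control they ranged from 5.87 per Mb (chromosome 14) to 10.6 per Mb (chromosome 11), with a median of 8.11. In the ZFP57 list the median was 2.83 and chromosome 19 was highest at 3.89, and in the KAP1 list the median was 1.85 and chromosome 17 was highest at 2.90 per Mb. The X chromosome held 0.917 isolated control regions per Mb (95% Poisson interval 0.776 to 1.08), 0.618 for ZFP57 and 0.691 for KAP1. The autosomal median was 8.84, 4.59 and 2.68 times the X value. Counting all regions, X held 2.32% of the control, 4.61% of the ZFP57 and 5.51% of the KAP1 list, and 7 of the 47 KAP1-rich windows. Chromosome 8 held 10.4 isolated control regions per Mb (9.82 to 10.9), the second highest autosome, ranked 2 in the KAP1 list as well (2.57 per Mb), and ranked 13 in the ZFP57 list (2.67 per Mb). It held 6.78% of the isolated control regions, 6.90% of the KAP1 and 4.84% of the ZFP57 ones.

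The low X value is not accounted for by gene number. A line through the 19 autosomes on protein-coding genes per Mb puts X at 7.25 isolated control regions per Mb, and X lay -6.33 from it, where the autosomes lay between -1.72 and 2.42. The number of X copies in each culture and the share of X sequence that short reads can be mapped to stay open and were not tested. The Y chromosome held 358 control, 334 ZFP57 and 310 KAP1 regions, of which 15, 11 and 7 were isolated. Whether these regions reflect a Y chromosome in each culture was not tested. For chromosome 8, extra copies in the control culture, a change known in ES cells, would raise the whole chromosome. Isolated control regions exceeded the median of the other autosomes in 10 of the 13 bins of 10 Mb, as did KAP1 regions in 10 and ZFP57 regions in 6. For the control this is fewer than the 11 set beforehand for that explanation and more than the 9 set against it, so copy number cannot be told apart from local features of the chromosome. Against the line on gene number, fitted without it, chromosome 8 lay 2.56 per Mb above in the control, outside the other autosomes (-1.56 to 1.20). Chromosome 8 was examined because its control value was high, so this is description and not a test. It lay 0.68 above for KAP1, inside their range (-0.46 to 0.81), and -0.20 from the line for ZFP57.

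ZFP57 and KAP1 regions coincided away from any control region. Clustering of every library in the same neighbourhoods was examined beyond 10 kb. There 68.0% of the 269 shared ZFP57 regions had a KAP1 midpoint within 50 bp (exact 95% interval 62.1 to 73.6%), where evenly spread offsets give 33.8%. This argues against loose clustering with evenly spread offsets as the only source of the sharing. Over all ZFP57 overlaps with control regions, without a distance limit, the value was 70.5%. Counted at least 10 kb from the third list, it was 60.5% for ZFP57 with control regions and 56.0% for KAP1 with control regions. These lie below the 68.0% for ZFP57 and KAP1 but above the even share. Close midpoints are therefore not particular to ZFP57 and KAP1. Moving each ZFP57 region by 0.5 to 5 kb left 2.85% of the sharing beyond 10 kb, 15.3% without control overlap and 39.2% with all regions kept. Leaving out regions near the control removes shared neighbourhoods beforehand, so the small remainder cannot decide the question. Background common to any pair of libraries stays open. The ratio to chance for ZFP57 and KAP1 was 3.65 times the larger of the ratios with the control, but if the strongest control regions carried all the sharing with ZFP57, a control set as long as the KAP1 set would reach a ratio of 308, above the 146 observed for ZFP57 and KAP1. Common binding of ZFP57 and its known cofactor KAP1 is the explanation the design names, and it may account for these 249 loci. It is a hypothesis that needs replicates, scores and both ChIPs in the same cells.

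The 1 Mb windows in which KAP1 regions outnumbered control regions were set against gene families by chromosome, as a test of whether such windows may be clusters of zinc finger genes, a class of gene known to be bound by KAP1. Over 20 chromosomes, which are not replicates, the number of windows and of Zfp genes gave Pearson's r = 0.40 (permutation p = 0.0744, adjusted over 3 gene groups 0.223) and Spearman's rho = 0.22 (permutation p = 0.348, adjusted 0.521). Without chromosomes 7 and 17, the farthest from the median number of Zfp genes, r was 0.05. It was 0.04 without chromosome 7 alone (90 Zfp genes, 7 windows) and 0.42 without chromosome 17 alone (41 Zfp genes, 2 windows), so Pearson's r rests on chromosome 7. Olfactory receptor genes, a family in tandem copies taken for comparison, gave r = -0.02 (permutation p = 0.955, adjusted 0.955) and rho = -0.27 (permutation p = 0.246, adjusted 0.521), and r = -0.50 without chromosomes 2 and 7. All protein-coding genes gave r = 0.18 (permutation p = 0.446, adjusted 0.668) and rho = 0.14 (permutation p = 0.545, adjusted 0.545). Whole chromosomes are too coarse to decide either explanation, and gene positions of build mm9 were not used here.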
